A study of Mus musculus with 4 samples.

How the data were processed

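Total RNA from neuron-enriched mouse dorsal root ganglion cultures was labelled with biotin and measured on Illumina bead arrays, with 2 samples treated with vehicle and 2 with Wnt3a. Per the labels' protocols, ganglion cells were passed over a Percoll gradient and kept for 3 days in medium with 10% serum. The medium held BDNF and NGF at 10 ng/ml each, GDNF and NT3 at 5 ng/ml each and the mitotic inhibitor AraC at 5 µM. The cultures were then starved of serum for 1 h and treated for 6 h. The labels disagree on the age of the mice, with 4 to 6 weeks in the sample characteristics and 6 to 8 weeks in the growth protocol.

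The values analysed were the intensity values deposited by the authors, on a linear scale and for each probe and array. They include values below 0 (24.5% to 24.6% of probes per array) and have nearly equal quartiles in the 4 arrays, which are the marks of background subtraction and of normalization between arrays before they were deposited. BeadStudio 3.2 is named in the submitters' processing notes, and the method of normalization is not given in the sources used here. A table of non-normalized signals was not used, because its 8 columns of signals and detection p-values carry names that match no sample's labels. The test fixed before the data were examined had been written for those signals, with normexp background correction, and its stated fallback, the deposited values, was used in its place. Quantile normalization was not needed for these values and was run as an alternative.

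Values below 0 were set to 0, 16 was added and log2 was taken, so every difference is on the log2(intensity + 16) scale, which understates the change of dim genes. Detection p-values were not used, so a detection limit was set for each array from the deposited values below 0, a choice made after the files had been examined. The limit was 1.645 times their root mean square about 0, the normal equivalent of a one-sided p of 0.05, and came to 17.1 in each array. Probes above the limit in at least 2 arrays were kept, 12025 of 25697, and 46.0% to 46.1% of probes lay above it on each array. The platform annotation gave 1 gene symbol for 23978 probes, several for 0 and none for 1719, which are unnamed here. A table of RefSeq genes for the assembly GRCm38.p6 was used only for names, and the Entrez identifiers of 23962 probes matched it. No coordinates are given, since the files name no genome build. The brightest kept probe stood for each gene, which left 8565 genes, and 696 kept probes had no symbol and were not tested. Where the probes of a named gene disagree in direction, the values of the other probes are given. A gene whose probe was under the limit on every array of a group has only a bound. The bright group's mean log2 value was set against the dim group's mean of, per array, the higher of the lowest signal above the limit and the probe's own signal.

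Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates, Benjamini-Hochberg adjustment over all 8565 genes), and a gene was called at an adjusted p under 0.05. The fit had 2 residual and 3.29 prior degrees of freedom. The number of genes at least 1.5-fold apart with no overlap between groups was counted as a description. Before the data were examined 24 gene lists were fixed, among them pathway genes and markers of neurons, glia, fibroblasts, macrophages and vessels. Lists were tested two-sided with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, with adjustment over the 24 lists. With an estimated correlation camera rests on the 2 residual degrees of freedom, so it has little power here. Its power was not simulated. Members were also adjusted over their list alone, which does not correct for the number of lists. Some genes stand in more than 1 list. The genes named in the text followed a rule fixed before the data were examined. Since no gene passed, they are the 12 genes in each direction with the smallest unadjusted p among those with no overlap between groups and a log2 difference of at least 0.3. To these were added the 2 detected members of each list with the smallest p and 10 fixed Wnt and NFAT targets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

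The test was run on simulated data with the 8565 genes of this comparison, 20 times with 200 changed genes. It gave an unadjusted p under 0.05 to 5.12% of unchanged genes and called 3.9 unchanged genes per simulation. Camera called a list shifted by 0.5 in 20 of 20 simulations and 0% of the unshifted lists. The simulated genes varied independently, so this rate does not cover lists whose members vary together on the real arrays. The shift of 0.5 was larger than any list median found in the main setting, of which the highest was 0.32. Smaller list shifts were not simulated.

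Alternatives were an offset of 50, a stricter limit in all 4 arrays, no filter, the mean of a gene's probes, every probe separately, an intensity trend with and without robust variance, the replicate number as a block and each array left out in turn. Quantile normalization, median scaling, cyclic loess and the combinations of offset 50 with the block were added after seeing the data. Precision is limited by the number of arrays.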

Results

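Gene expression was measured in cultures enriched for sensory neurons, prepared from the dorsal root ganglia of C57Bl/6 mice. Dorsal root ganglia lie beside the spinal cord and hold the cell bodies of the neurons that carry touch, temperature and pain signals, surrounded by satellite glia, Schwann cells, fibroblasts, vessels and resident macrophages. The cultures received Wnt3a, a secreted ligand that activates β-catenin signalling through Frizzled and LRP receptors, at 200 ng/ml, or its vehicle, phosphate-buffered saline. RNA was taken after 6 h and hybridised to Illumina bead arrays, 1 array per sample, with 2 vehicle and 2 Wnt3a samples. The arrays had mean normalized intensities between 327.9 and 330.2, and between 11822 and 11836 of 25697 probes lay above the detection limit on each. The design has 1 comparison, Wnt3a against vehicle, which asks which transcripts in these cultures differ after 6 h of exposure to the ligand. The number of arrays limits the precision, and since nothing in the labels says that the samples came from separate cultures or animals, p-values measure the spread between these 4 samples, which may be technical.

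Among the best-separated transcripts, Egr2, Ctsc, Cyp2d22 and Dhh lay about 2-fold or more higher with Wnt3a, Inmt and Sox18 more than 2-fold lower, and the β-catenin target Axin2 was higher in both Wnt3a arrays than in either vehicle array. None of these differences passed the test over all genes. In limma's moderated test 0 of 8565 genes reached an adjusted p under 0.05, and the smallest adjusted p was 0.9997. At an unadjusted p under 0.05 there were 381 genes, 208 higher and 173 lower with Wnt3a, against 428.2 that chance alone would give. Irrespective of the test, 341 genes differed at least 1.5-fold with no overlap between the groups, 202 of them higher and 139 lower with Wnt3a. With offset 50 the count was 85, and without Wnt3a replicate 2 the balance turned to 304 higher and 340 lower. In 105 of the 341 genes, 1 group lay wholly under the detection limit. Over all genes 30.1% had groups that did not overlap, where chance gives 33.3% for 2 arrays against 2. Grouping the same 4 arrays in the other ways gave 390 and 421 such genes, more than the real grouping. In simulated data built on these arrays, with 200 changed genes, the same test recovered 72.1% of 4-fold changes and 3.15% of 2-fold changes. The adjustment is stricter where fewer genes change, so these shares do not carry over to a smaller response. A fit of every probe with a larger offset of 50 and the replicate number as a block, chosen after seeing the data, was the one exception among the settings run, with 10 genes at a limma adjusted p under 0.05. Egr2, Ctsc, Mfsd2a and Pvalb were the higher of these 10 genes. The other 6 were lower with Wnt3a and had their lowest value in Wnt3a replicate 1, and in the same setting the replicate number itself separated 66 genes.

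The genes with the smallest p among those higher with Wnt3a had varied known functions, and all log2 differences here and below are Wnt3a minus vehicle with the standard error of the limma fit. Egr2, a zinc-finger transcription factor that is both an immediate early gene and a regulator of Schwann cell myelination, had log2 intensities of 7.85 ± 0.13 with vehicle and 9.23 ± 0.14 with Wnt3a (SD, n = 2 each), a difference of 1.39 ± 0.18. Ctsc, which encodes the lysosomal peptidase cathepsin C, differed by 1.56 ± 0.26, and its 3 probes gave differences between 1.51 and 1.57. Dhh, the desert hedgehog ligand of Schwann cells, differed by 0.99 ± 0.18 and the cytochrome P450 gene Cyp2d22 by 1.30 ± 0.22. Nhsl1, Mmd2 and Nudt21, the last a subunit of a pre-mRNA cleavage factor, differed by 1.01, 1.05 and 1.00, with Nudt21 above the limit on only 1 of 2 vehicle arrays. The remaining 5 genes were not above the detection limit on either vehicle array, so that their differences have only a lower bound. Mfsd2a, a lysophospholipid transporter, was at least 2.61-fold higher, and Sostdc1, a secreted antagonist of BMP and Wnt ligands, at least 2.30-fold higher. Spns1, Tmem47 and C1qa, a chain of complement C1q, were at least 1.43-fold, 1.26-fold and 1.16-fold higher. All 12 genes had a limma adjusted p of 0.9997.

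On the lower side most of the best-separated genes were dim. Inmt, a methyltransferase of indolethylamines, stood at 6.82 ± 0.27 with vehicle and 5.59 ± 0.02 with Wnt3a (SD, n = 2 each), a log2 difference of -1.23 ± 0.20. Sox18, a transcription factor of endothelial cells, differed by -1.13 ± 0.24 and was above the limit on all 4 arrays. Hykk and Ube2j2 differed by -0.90 and -0.82 and were above the limit on only 1 of the 2 Wnt3a arrays. A second probe of Ube2j2 gave -0.09. Vehicle exceeded Wnt3a by at least 1.66-fold for Idi2, 1.63-fold for Mnt, 1.37-fold for the neuronal adhesion gene Negr1, 1.17-fold for Shroom1, 1.15-fold for Rabepk and 1.15-fold for the carbonic anhydrase gene Car9. For the olfactory receptor genes Olfr1346 and Olfr297 the bounds were 1.05-fold and 1.04-fold. The Wnt3a arrays held no signal above the limit for these 8 genes. The limma adjusted p was 0.9997 for all 12 genes of this side.

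**Figure D1:**
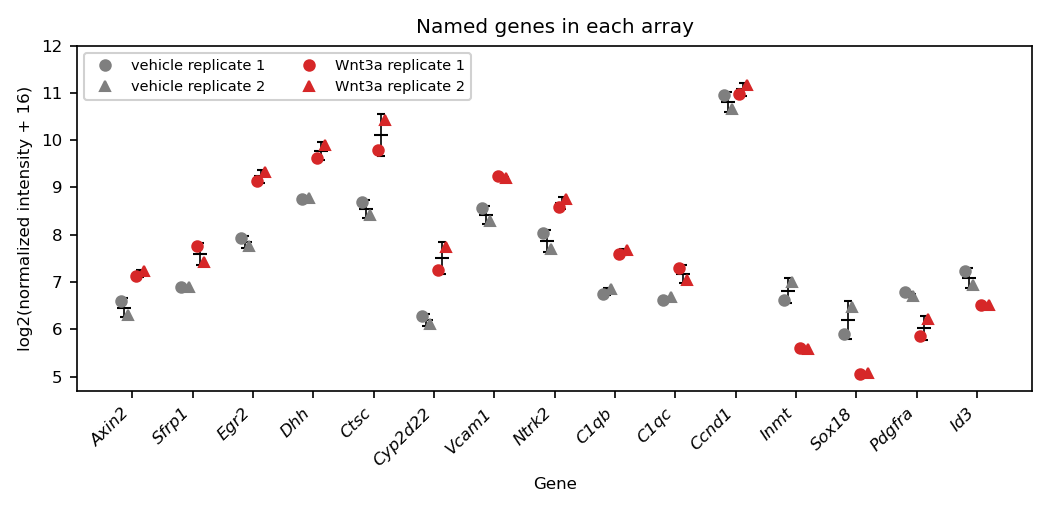
Log2 normalized intensity (with 16 added) of 15 genes in each of the 4 arrays, with vehicle in grey and Wnt3a in red, circles for replicate 1 and triangles for replicate 2, and black bars for the group mean ± SD (n = 2). Egr2 and Ctsc differed by 1.39 and 1.56 with no overlap between the groups, while Ccnd1 differed by 0.26. None of the genes passed the limma test over all genes, and C1qc was added after its values were seen.

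Targets of β-catenin were examined first because they report canonical Wnt signalling. Axin2, a scaffold of the β-catenin destruction complex whose transcription β-catenin induces, had a log2 intensity of 6.45 ± 0.20 with vehicle and 7.18 ± 0.07 with Wnt3a (SD, n = 2 each). Its difference of 0.73 ± 0.19 corresponds to 1.66-fold, with an unadjusted limma p of 0.00997 and an adjusted p of 0.9997. Apcdd1, a membrane-bound Wnt inhibitor, differed by 0.79 ± 0.30, with a signal above the limit on 1 vehicle array. This difference was 0.40 without vehicle replicate 2 and 1.19 without vehicle replicate 1. The cyclin gene Ccnd1 differed by 0.26 ± 0.20 in its brightest probe and by 0.44 and 0.36 in the others, and Myc differed by -0.02 ± 0.24. Nkd1, Lef1, Sp5, Notum and Lgr5 were not above the detection limit on any array. Of 35 listed targets 14 were detected, 9 higher and 5 lower with Wnt3a, and 0 passed either over all genes or adjusted over the list alone. The list had a median difference of 0.10 and a camera adjusted p of 0.201. Without vehicle replicate 1 the median was 0.36 and the list was called (camera adjusted p = 0.00170), which no other array left out gave.

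The Wnt ligands and secreted antagonists shifted upwards in the camera test (median 0.17, adjusted p = 0.0405). The median ran from 0.03 to 0.36 with 1 array left out. With an estimated correlation of 0.03 camera's adjusted p was 0.820, in a form of the test with little power here. Of its 9 detected members 7 were higher with Wnt3a. Sostdc1, under the limit on both vehicle arrays, passed when adjusted over the list alone (limma adjusted p = 0.00811). The secreted Frizzled-related protein gene Sfrp1 differed by 0.69 ± 0.19. The higher members of this list are antagonists as well as ligands, and without 1 array the list was called only where Wnt3a replicate 2 was left out. Receptors and intracellular components of the pathway were not called (25 detected, median 0.10, camera adjusted p = 0.394). Among them Fzd6, a Frizzled receptor, was at least 1.35-fold higher with Wnt3a, and the 2 probes of the kinase gene Mapk10 gave opposite differences of -0.46 and 1.01. The calcineurin and NFAT genes of the calcium branch of Wnt signalling had a median of 0.04 and a mean of -0.03 over 21 detected members, with a camera adjusted p of 0.703. Prkcd and Ppp3cc, a protein kinase C and a calcineurin catalytic subunit, differed by -0.30 ± 0.19 and -0.26 ± 0.16. The NFAT target Rcan1 differed by -0.07 ± 0.18 in its brighter probe and by 0.51 in the other, and the NFAT target Ptgs2 was not above the limit on any array.

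Immediate early genes were not called as a list (median 0.03 over 23 detected members, camera adjusted p = 0.168). They were called upwards with the mean of a gene's probes (adjusted p = 0.0280), every probe separately (0.0383), every probe with offset 50 and the block (0.0117), without vehicle replicate 1 (0.0364) and without Wnt3a replicate 1 (0.0249). Egr2 passed when adjusted over the list alone (limma adjusted p = 0.0109). Ier3 differed by 0.62 ± 0.23, and by 0.39 without vehicle replicate 2 and 0.86 without vehicle replicate 1. TGF-β and BMP targets had a median of 0.03 and a mean of -0.01 over 15 members (camera adjusted p = 0.787). Within it Tgfb1 differed by 0.58 ± 0.17 and the BMP target Id3 by -0.58 ± 0.19. Notch targets had a median of 0.22 over 10 members with a camera adjusted p of 0.201. Nrarp, a feedback regulator of Notch, differed by 0.40 ± 0.19, and the 2 probes of Dtx4 gave -0.81 and 0.33.

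No list of neuronal genes was called with all 4 arrays, and 3 of them were called when 1 array was left out. The 18 detected markers of sensory neurons had a median of 0.07 (13 higher, camera adjusted p = 0.191). Without vehicle replicate 2 their median was 0.17 (adjusted p = 0.0305) and without Wnt3a replicate 2 it was 0.19 (adjusted p = 0.0412). Thy1, a surface glycoprotein, and Nefh, the heavy neurofilament, differed by 0.67 ± 0.31 and 0.63 ± 0.34. In both genes vehicle replicate 1 was the lowest array by over 0.8, with Thy1 at 11.82 there against 12.68 in vehicle replicate 2. Nociceptor channels and receptors had a median of 0.01 over 23 members (camera adjusted p = 0.394), of 0.34 without vehicle replicate 2 (adjusted p = 0.00208) and of -0.20 without vehicle replicate 1, where it was not called. Ntrk2, the receptor for BDNF, differed by 0.81 ± 0.20, and the channel gene Hcn3 by -0.46 ± 0.17, with -0.45 and -0.93 in its dimmer probes. Neuropeptides and neurotrophic factors had a median of 0.14 over 17 members (camera adjusted p = 0.168). Artn, encoding the neurotrophic ligand artemin, differed by 0.66 ± 0.22 and Gdnf by 0.70 ± 0.36, the latter with overlapping groups. With 1 array left out the values ran from 0.43 to 0.89 for Artn and from 0.32 to 1.08 for Gdnf. Genes of nerve injury and regeneration had a median of -0.04 over 25 members (camera adjusted p = 0.682), among them Ecel1 at -0.39 ± 0.17 and Serpinb1a at 0.42 ± 0.21, the latter 0.20 without Wnt3a replicate 2 and 0.64 without Wnt3a replicate 1. Synaptic vesicle and transmission genes had a median of 0.06 over 21 members (camera adjusted p = 0.201), and of 0.10 without vehicle replicate 2 (adjusted p = 0.0305). The complexin gene Cplx1 differed by 0.45 ± 0.21, and the 2 probes of the glutamate receptor gene Gria2 gave 0.48 and -0.31.

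Markers of macrophages shifted upwards as a list, with 10 of 14 detected members higher with Wnt3a, a median of 0.32 and a camera adjusted p of 0.00134. With an estimated correlation camera's adjusted p was 0.820. That correlation was -0.06, below the preset one, so the lost call is no sign of members that vary together. The 11 members other than the C1q genes had a mean of 0.18 with a 95% interval over genes from -0.08 to 0.44. Among them Mrc1, Cd14 and Laptm5 differed by 0.98, 0.50 and 0.35, and Cx3cr1 by -0.39, each with groups that did not overlap. Tyrobp, Ctss and Aif1 differed by -0.03, -0.08 and 0.02. In the whole list, C1q genes included, groups did not overlap in 6 higher members and 1 lower member. The list's median was 0.28 with C1qa and 1 other member at their lower bounds. C1qa and C1qb, both chains of complement C1q, passed when adjusted over the list alone (limma adjusted p = 0.0180 and 0.0231). C1qa was under the limit on both vehicle arrays. C1qb stood at 6.80 ± 0.07 with vehicle and 7.64 ± 0.06 with Wnt3a (SD, n = 2 each). Rotation testing of the list by itself with fry gave an adjusted p of 0.276 for a shift in 1 direction and 0.0228 for change in either direction, the only list with a fry call of the second kind. The macrophage list was the only one called by camera without each array in turn, with medians between 0.20 and 0.38. It had been called on these same arrays, so this is no independent support.

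Cell cycle genes shifted upwards in camera, with all 21 detected members higher with Wnt3a, a median of 0.27 and an adjusted p of 0.00134. The estimated correlation between members was 0.51, far above the preset 0.01, and with it camera's adjusted p was 0.820. These genes thus varied together on the arrays. The vehicle arrays differed from each other by a mean of 0.54 over them, more than the groups did (mean 0.30). Groups did not overlap in only 3 of the 21 genes. The mitotic kinase gene Cdk1 differed by 0.45 ± 0.18. Top2a, a topoisomerase of dividing cells, differed by 0.82 ± 0.40, with values of 6.71 and 5.82 in the vehicle arrays and 6.69 and 7.48 in the Wnt3a arrays. The cell cycle shift rested on vehicle replicate 2 and Wnt3a replicate 2, since the list was not called without either of them. Markers of Schwann cells and satellite glia shifted upwards in camera with 8 of 11 members higher (median 0.24, adjusted p = 0.0373). With an estimated correlation of 0.11 camera's adjusted p was 0.820. With 1 member at its bound the median was 0.22. Art3 differed by 0.70 ± 0.25, with signal above the limit on 1 vehicle array, and S100b was at least 1.16-fold higher. Without vehicle replicate 2 or without Wnt3a replicate 2 the glial list was not called.

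Fibroblast and perineurial markers had a median of -0.12 over 15 members, 11 of them lower with Wnt3a, and did not pass (camera adjusted p = 0.168). Pdgfra, a PDGF receptor of fibroblasts, differed by -0.71 ± 0.20 and the matrix gene Fbln2 by 0.61 ± 0.18. The fibroblast list was called without vehicle replicate 2 (median -0.49, camera adjusted p = 6.821e-04) and without Wnt3a replicate 2 (median -0.42, adjusted p = 0.00948), and with every probe, offset 50 and the block (adjusted p = 0.0476). Median levels of this list lay 0.38 above the 4-array mean in vehicle replicate 1 and between -0.30 and 0.04 in the other arrays. Endothelial and pericyte markers had a median of -0.17 over 16 members (camera adjusted p = 0.379), with Tie1 and Myh11 at least 1.31-fold and 1.44-fold higher. Both were highest in Wnt3a replicate 1, where Tie1 stood at 5.77 against 5.10 in Wnt3a replicate 2, and Myh11 at 5.80 against 5.35. Taken without the bound, their log2 differences were 0.88 and 0.67, and 0.54 and 0.45 without Wnt3a replicate 1. Cytokines, chemokines and NF-κB targets had a median of -0.08 over 24 members (camera adjusted p = 0.394). The direction depended on the arrays, with calls at medians of 0.0715 without vehicle replicate 1, -0.35 without vehicle replicate 2 and -0.31 without Wnt3a replicate 2 (adjusted p = 0.0315, 0.0228 and 0.00948). The adhesion molecule gene Vcam1 differed by 0.80 ± 0.18, and Tnfaip3, an inhibitor of NF-κB, was at least 1.26-fold higher. Interferon-stimulated genes had a median of 0.14 over 20 members (camera adjusted p = 0.0910). They were called upwards without Wnt3a replicate 1 (median 0.35, adjusted p = 6.172e-07), without vehicle replicate 1 (median 0.22, adjusted p = 0.0172) and with every probe, offset 50 and the block (adjusted p = 0.0476). Over the arrays left out their median ranged from -0.09 to 0.35. Oasl1 was at least 1.13-fold higher and Oasl2 differed by 0.50 ± 0.28, and by 0.14 and 0.86 without Wnt3a replicates 2 and 1.

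**Figure D2:**
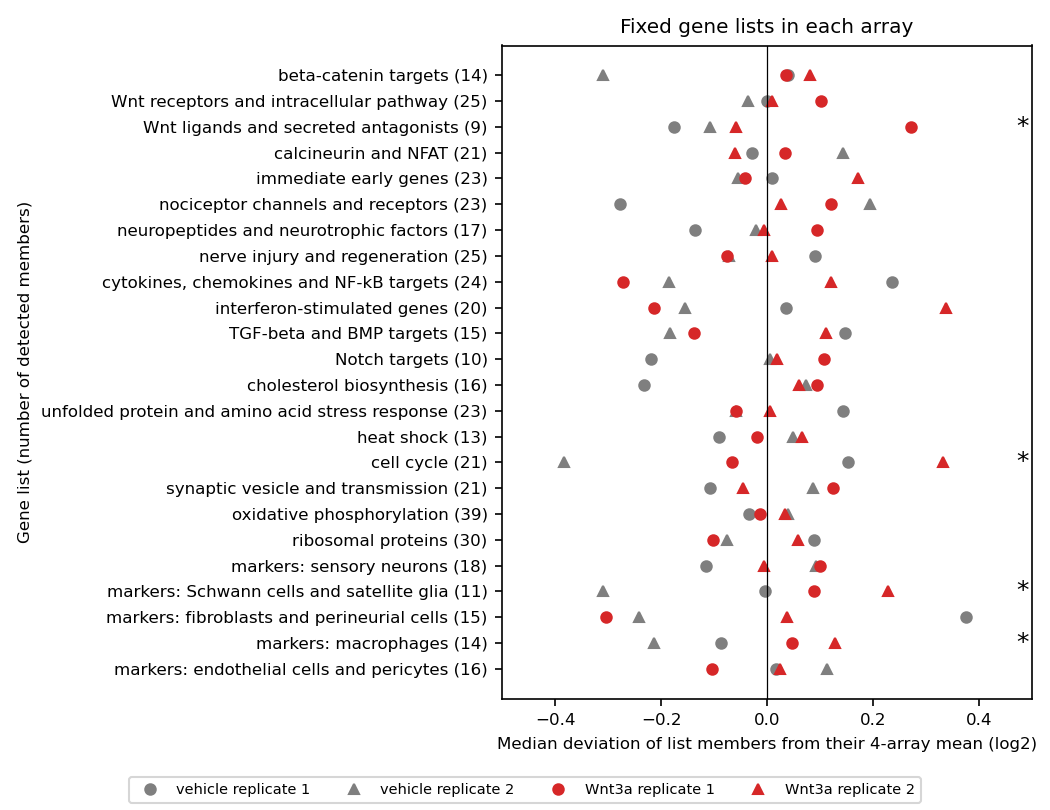
Median log2 deviation of each list's detected members from their 4-array mean, in each of the 4 arrays (vehicle grey, Wnt3a red, circles for replicate 1, triangles for replicate 2), with the number of members in brackets and an asterisk where camera's adjusted p was under 0.05. The macrophage list had both vehicle arrays at -0.09 and -0.21 and both Wnt3a arrays at 0.05 and 0.13, whereas the cell cycle list had vehicle replicate 1 at 0.15, above Wnt3a replicate 1 at -0.07.

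Lists of general cell functions were not called with all 4 arrays in the main setting. Cholesterol biosynthesis genes had a median of 0.12 over 16 members (camera adjusted p = 0.168), with Cyp51 at 0.33 ± 0.20 and Lss at 0.29 ± 0.18. This list was called without vehicle replicate 2 (median 0.28, adjusted p = 0.0228) and with every probe, offset 50 and the block (adjusted p = 0.0476). Stress genes of the unfolded protein and amino acid responses had a median of -0.04 over 23 members (camera adjusted p = 0.365), with Nupr1 at -0.54 ± 0.26 and Chac1 at -0.29 ± 0.17. Without vehicle replicate 2 it was called at a median of -0.22 (adjusted p = 0.0228). Heat shock genes had a median of 0.03 over 13 members (camera adjusted p = 0.394). The small heat shock protein gene Cryab differed by 0.60 ± 0.24 and Hspa1a by -0.42 ± 0.21. With 1 array left out the values ran from 0.40 to 0.81 for Cryab and from -0.61 to -0.24 for Hspa1a. Oxidative phosphorylation genes had a median of 0.00177 over 39 members (camera adjusted p = 0.674), with Sdhd at -0.44 ± 0.21 and Cox6c at 0.37 ± 0.18. Ribosomal protein genes had a median of -0.03 over 30 members (camera adjusted p = 0.5005), and of -0.12 without Wnt3a replicate 2 (adjusted p = 0.0499). Rpl24 differed by -0.27 ± 0.18, and the 3 probes of Rpl23 gave -0.38, 0.01 and 0.09. In total camera called 4 of 24 lists with its preset correlation and 0 with an estimated correlation, and fry called 0 for a shift in 1 direction. With offset 50, the stricter limit or an intensity trend the Wnt ligand and glial lists were not called, and with no filter the macrophage list alone was. With every probe separately the glial list was not called and immediate early genes took its place. A different grouping of the 4 arrays gave 15 camera calls, more than the 4 of the real grouping. Each side of it held 1 vehicle and 1 Wnt3a array, so the preset correlation can give calls here without a treatment difference. Estimated correlations in the real grouping ran from -0.06 for macrophage markers to 0.66 for ribosomal protein genes, against the preset 0.01. With an estimated correlation every grouping gave 0. That form has little power here, which was not simulated, so its 0 does not tell the groupings apart.

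The replicates of vehicle lay further apart than those of Wnt3a. The vehicle arrays had a Pearson correlation of 0.976 over genes, which are not independent replicates, and an SD of the log2 difference of 0.47. The Wnt3a arrays had a correlation of 0.986 and an SD of 0.36. Pairs of 1 vehicle and 1 Wnt3a array had correlations between 0.980 and 0.984, so that each such pair was more alike than the vehicle replicates were. Of the 72 named genes that were detected, 29 moved by more than 1.5 times or turned direction when 1 array was left out. The brightest probe was chosen anew each time, so some of these moves, as for Dtx4 and Ube2j2, reflect a change of probe. The medians of 13 of the 24 lists turned direction when 1 array was left out, 0 of them among the 4 called lists. Those 4 had been called on these same arrays, so their steady direction is no independent support.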

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

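The combined offset and block settings, quantile normalization, median scaling and cyclic loess were chosen after seeing the data. In limma 0 genes passed under the main setting and under each alternative but 1. With every probe, offset 50 and the replicate block together 10 genes passed (Erich5, Rhbdl2, Prf1, Gm7609, Zxda and Ccdc144b lower, and Ctsc, Egr2, Pvalb and Mfsd2a higher), 94 genes were 1.5-fold apart and 8 lists were called. Blocking on the crossed pairs in that setting passed 0 genes, and the cause was not tested. With all 4 arrays, the count at an unadjusted limma p under 0.05 was 381 of 8565 genes tested in the main setting. It ranged from 227 of 7046 with the stricter limit to 1136 of 16593 with no filter. The totals tested differ, so these counts cannot be compared directly.

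The 341 genes at least 1.5-fold apart became 85 with offset 50, with or without the block, which by construction shrinks differences of dim genes. They became 137 above the 0.01 limit in all 4 arrays and 734 with no filter, which change the genes counted. Without 1 array the count lay between 622 and 932, since 1 array against 2 overlaps less often. Of these genes 59.2% were higher with Wnt3a, against 68.2% with offset 50, 50.4% with no filter and 47.2% without Wnt3a replicate 2, and 59.2% to 60.9% under the scalings. The 4 called lists became 2 with offset 50 (with or without the block), 2 with the stricter limit, 2 with either intensity trend and 1 with no filter. They became 0 with an estimated correlation and 0 with fry for a shift in 1 direction (1 in either direction), and 5 to 8 without 1 array. The causes of the changes in lists were not tested. Cytokines, chemokines and NF-κB targets had a median of -0.08 and reversed to 0.0715 without vehicle replicate 1 (camera adjusted p = 0.0315). Their median ranged from -0.346 to 0.0715 over the arrays left out and their adjusted p from 0.00948 to 0.960 over all alternatives. When 1 array is left out, the lone array of its group is assumed to vary like the other group.

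The series describes the vehicle culture as matched, without saying that replicate numbers mark pairs, and same-numbered samples did not deviate together (correlation 3.592e-04 over genes). With the replicate block alone 0 genes passed and 4 lists were called. Of the values of single genes under the alternatives 1183 kept their side and direction, 3 newly passed and 10 moved across 0. Of those of lists 379 kept theirs, 22 were newly called, 28 lost their call, 25 moved across 0 and 1 reversed. The count for genes was largely fixed in advance and is no measure of robustness. No gene passed in the main setting, and many of the named genes had been chosen for groups that did not overlap. Not run were the signals without background correction, the scalings after normexp, and a slide block, since the files name no slides. Signal over background limits the dim genes, which have only bounds.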

Other observations

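All tests of explanations here were chosen after the results were seen, apart from the test of array scaling, whose bound was set before its value was computed but for a pattern, and with a method, chosen after seeing the data.

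Some genes had a value in vehicle replicate 1 unlike that in the other 3 arrays, and the examples given here were chosen after their values were seen and stand for no tested theme. Pvalb, a calcium-binding protein of proprioceptors, had a log2 intensity of 7.36 there against 8.77, 9.43 and 9.76 in vehicle replicate 2 and the Wnt3a arrays. Cntn1, an axonal adhesion molecule, stood at 6.97 there and between 8.23 and 8.91 elsewhere. The synaptic vesicle gene Sv2b stood at 6.84 and between 8.46 and 8.53 elsewhere. The matrix genes Lum and Ogn were higher there, with 8.78 and 7.30 against at most 7.50 and 6.07 elsewhere. In this array 37 genes were lower by at least 1 (log2) than in every other array and 20 were higher. The counts were 18 and 2 for vehicle replicate 2, 13 and 1 for Wnt3a replicate 1, and 0 and 7 for Wnt3a replicate 2. Interferon-stimulated genes had their highest list median in Wnt3a replicate 2, with Usp18 at 9.13 there and 7.33 in Wnt3a replicate 1, and Calb2, a calcium-binding protein, stood at 7.01 there and at most 5.27 elsewhere.

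The vehicle arrays differed more from each other than any other pair. The SD of their log2 difference was 0.47 before and 0.4668 after cyclic loess, against 0.36 for the Wnt3a pair. The deposited values thus hold no intensity-dependent scaling difference that loess removes. They were already normalized between arrays, so this cannot test such a difference before normalization. A lower share of neurons that raises all other cell types alike is argued against, since fibroblast markers exceeded endothelial and pericyte markers by 0.73 in the difference between the vehicle arrays (95% interval over genes 0.39 to 1.07). The intervals in this paragraph describe these 2 arrays, and they are too narrow where markers of 1 cell type vary together. More fibroblast and perineurial cells in vehicle replicate 1 may be part of it: 14 of 15 of their markers were higher there, with a mean of 0.58 and a lower bound of 0.34, while neuron markers had a mean of -0.29 and nociceptor genes -0.52. Other lists moved with the fibroblast markers, with 19 of 21 cell cycle genes higher there (mean 0.54, 95% interval over genes 0.30 to 0.78) and Schwann and satellite glia markers at 0.44 (-0.07 to 0.95). The abundant fibroblast transcript Dcn stood at 11.04 there and 10.18 in vehicle replicate 2, 0 of the 15 fibroblast markers stand in another list, and the Percoll gradient and AraC of the protocol would lower such cells. A difference in the state of these cells rather than in their number stays open. Both arrays belong to 1 group, so the design names no biological difference between them.

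The complement C1q genes were higher in both Wnt3a arrays than in either vehicle array, and C1qb and C1qc had a mean difference of 0.68 (0.84 and 0.52). A higher share of macrophages in the Wnt3a cultures is a candidate explanation, as is a response of macrophages to Wnt3a, which the design does not separate from it. Chance is another, since no gene passed over all genes and the C1q genes were taken up after their values were seen. The 5 brightest other macrophage markers (Adgre1, Fcer1g, Lyz2, Laptm5 and Lgals3) had a mean difference of 0.20 (Lyz2 0.35 and the brightest, Lgals3, -0.26), and C1qb and C1qc exceeded them by 0.48. With 2 arrays per group the 95% interval of that excess ran from -0.71 to 1.67, so the explanations cannot be told apart. A first form of this test, with C1qa and an interval over genes, had excluded a higher share as the whole cause, but C1qa has only a bound, and an interval over genes leaves out the spread between arrays that a difference between groups must exceed.

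A group of 9 genes, Rhbdl2, Ccdc144b, Ern2, Gm7609, Pisd-ps2, Prf1, Sftpd, Sox21 and Zxda, was picked out by a common profile over the 4 arrays. Each was lowest in Wnt3a replicate 1, correlated with Rhbdl2 at 0.98 or more and was lower with Wnt3a by at least 1.5-fold, with a gap of at least 0.75 between the Wnt3a arrays, limits set after seeing the data. Genes chosen in this way correlate highly over 4 arrays by construction. By the fold, the gap and no overlap between groups, without the correlation, 14 genes had Wnt3a replicate 1 as their lowest array, and 2 had Wnt3a replicate 2, 35 vehicle replicate 1 and 17 vehicle replicate 2 in that role, so the number of such genes does not stand out. Rhbdl2 had values of 9.11, 9.33, 6.41 and 8.11 in the vehicle and Wnt3a arrays, and Erich5 looked alike without meeting the limit on correlation. Erich5 and 5 of the 9 genes are the 6 lower genes that passed with every probe, offset 50 and the replicate block. Probes that read 1 shared sequence rather than their own genes are a candidate explanation. Of the other probes of these genes 0 of 4 lay above the detection limit, against 44.8% of 2242 for equally bright genes (exact Fisher test, two-sided, p = 0.133), which is too few probes to decide. Whether the profile reflects Wnt3a also stays open, as it is set by 1 array.

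The 4 arrays can be grouped 2 against 2 in 3 ways, which is too few for a share under 0.05. For genes at an unadjusted p under 0.05 the real grouping gave 381 and the highest other 627, and all 3 groupings gave as many as the real one. For genes 1.5-fold apart the counts were 341 and 421, again with 3 of 3 as large. For lists called by camera they were 4 and 15, with 2 of 3 as large. The 15 lists were called when vehicle replicate 1 and Wnt3a replicate 2 were set against the others. Treatment does not differ between the sides of that grouping, so calls at the preset correlation can arise on these arrays without it. With an estimated correlation 0 of them held. That form of camera has little power here, which was not simulated, so this does not tell the groupings apart.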
